A study of Mus musculus with 6 samples.

How the data were processed

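RNA sequencing counts were taken from 6 mouse neurofibromas, 3 labelled miR155KO_Nf1KO and 3 labelled Nf1KO, with the group and the tumour number read from the sample titles. Per the labels' protocols, RNA was extracted with a Qiagen RNeasy Plus Micro kit and libraries were made with an Illumina Nextera XT kit. The authors deposited 1 table of whole-number read counts per gene symbol, with 1 column per tumour, and the counts were not scaled. Per the submitters' processing notes, HISAT2 2.0.5, featureCounts 1.5.2 and the genome build mm10 were used. The annotation, the strand setting and the treatment of reads that match several places are not given in the sources used here. Reads of overlapping or antisense genes, and of close copies within a gene family, may therefore have been shared or dropped, and the genes with the largest changes that have close copies are named as uncertain. The same limit holds for the ribosomal protein, Cd209a, Clec, Ifi and Ccl genes, which are not marked each time.

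The table held 24421 gene symbols, of which 4229 had no read in any tumour. The column totals ran from 13061129 to 16333181 reads. Counting error is small for most genes at this depth, and the spread between tumours sets the precision. The genes with the largest called changes that had under 12 reads in 1 group, a bound set after the data were seen, are given with a 95% exact binomial interval. It covers counting error only, since reads without molecular identifiers are not independent molecules. Replicate tumours of 1 group were compared first: their counts differed by at least 23.37 times the variance that Poisson sampling gives, so no library was counted as a repeat of another.

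Genes were compared with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test, two-sided, after filterByExpr (minimum count 10, minimum total count 15) and TMM scaling, with the group as the only term and Benjamini-Hochberg adjustment over the 15604 genes tested. A gene was called at an adjusted p under 0.05. Standard errors are those implied by the quasi-likelihood F statistic. CPM values are counts scaled to 1e6 reads of the TMM-scaled library size, given as mean ± SD over the 3 tumours of a group. Sex was read from the counts of Xist and of the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y. Principal components and correlations used log2 CPM with a prior count of 2.

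Before the data were examined, 37 cell type and pathway lists, 1 list of 42 miR-155 targets from the literature and 2 technical lists were fixed. Lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the 35 cell type and pathway lists that qualified. Camera with an estimated correlation and fry were run beside it. Counts of members are given over all genes tested and, separately, adjusted over the list alone. The list of mitochondrial transcripts had no member in the table, and the erythroid list and the epithelium and hair follicle list had too few tested members for a set test.

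Sites for miR-155-5p were sought in the longest annotated 3′ UTR of each gene in GENCODE M21 on GRCm38, the assembly that mm10 names. The sites were the 8mer AGCATTAA and its 7-base parts AGCATTA and GCATTAA. Of the gene symbols, 23376 matched the annotation, and 14015 of the tested genes had a 3′ UTR. The shift of site genes is the median log2 fold change of each site gene minus the median of genes without a site in the same bin of 3′ UTR length (10 bins) and mean expression (5 bins). The same quantities were computed for 419 shuffled heptamers of the same base composition, each scored as the heptamer or as its end followed by A. The controls GCATTAA and AAGCATT take in the miR-155 sites GCATTAA and AGCATTA by this rule, so the controls are not all free of miR-155 sites. Genes near the Mir155 locus were compared with genes elsewhere by a two-sided Fisher's exact test in scipy 1.17.1, within 10 Mb and, as alternatives, 5 and 20 Mb. All coordinates are 1-based on GRCm38.

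Named genes follow a rule fixed before the data were examined. They are Mir155hg, Mir155, Nf1 and Dhh. In each direction they include the 10 called genes with the largest log2 fold change, a mean log2 CPM of at least 1 and no overlap between groups, leaving out predicted genes. They also include the 4 members of each list with the smallest p, and the 10 genes higher in miR155KO_Nf1KO with an 8mer site and the smallest p. Other genes are marked where they are named as chosen after their values were seen. Some genes that the rule takes are not reported here.

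The alternatives were DESeq2 size factors, upper quartile scaling and total counts in edgeR, no low-count filter or a CPM of at least 1 in 3 tumours, DESeq2 1.42.0, limma voom with and without sample quality weights, edgeR with robust estimation, sex as a covariate, other thresholds, other site definitions and leaving out each tumour in turn. Fits without tumours MiRNC670 and Nf809, without tumours MiRNC149 and Nf809, and DESeq2 with 1 tumour left out were added after the data were seen.

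The steps were tested on simulated data with the means, dispersions and library sizes of these tumours. With 200 of 15604 genes changed, edgeR recovered 6 of 67 genes changed 2-fold, 37 of 67 changed 4-fold and 58 of 66 changed 8-fold, and called 8 of the 15404 unchanged genes. DESeq2 recovered 24, 56 and 60 and called 50 unchanged genes. A list of 25 genes raised by 1 log2 unit among 15359 genes gave p = 2.64e-28 by camera at the preset correlation and p = 2.50e-04 with an estimated correlation. Of 200 unchanged lists, 8 had an unadjusted p under 0.05 by camera and 0 with an estimated correlation, and fry gave 8. These genes were drawn independently of each other. In several real lists they moved together (estimated correlation 0.759 for sensory neuron and 0.598 for macrophage genes, against -0.0184 for fibroblast genes). The simulation therefore does not give the false positive rate of camera at the preset correlation on such lists. A rise of 0.2 log2 units put into site genes was recovered as 0.188 over 13864 genes, above all 419 control sites.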

Results

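RNA sequencing measured gene expression in 6 neurofibromas, benign tumours of the peripheral nerve sheath, from mice on a C57BL/6J background. In all of them a Cre recombinase under the promoter of Dhh, a gene of the Schwann cell lineage, removed floxed Nf1, which encodes a negative regulator of Ras. The 3 tumours of the group miR155KO_Nf1KO (MiRNC149, MiRNC640 and MiRNC670) also lacked the microRNA miR-155, and the 3 tumours of the group Nf1KO (Nf803, Nf809 and Nf827) did not carry that knockout. The stated aim of the comparison was to find possible miR-155 targets from expression differences. Totals ran from 13061129 reads in tumour MiRNC670 to 16333181 reads in tumour Nf809. By Xist and Y-linked counts, tumour MiRNC149 was female and tumours MiRNC640 and MiRNC670 were male, whereas tumours Nf803 and Nf827 were female and tumour Nf809 was male, and none of the 5 sex-linked genes was called between groups by edgeR. The labels number the tumours but do not say that each came from a separate animal, so p-values measure the spread between these samples.

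The transcript that carries miR-155 was almost lost in miR155KO_Nf1KO. Mir155hg, the host gene of miR-155 (ENSMUSG00000097418.7, chromosome 16, 84703167 to 84715245, plus strand), had 5, 3 and 1 reads in tumours MiRNC149, MiRNC640 and MiRNC670, against 57, 66 and 71 in tumours Nf803, Nf809 and Nf827. Its level was 0.201 ± 0.121 CPM (SD, n = 3) in miR155KO_Nf1KO and 4.32 ± 0.373 CPM (SD, n = 3) in Nf1KO, a decrease of 95.35%. The log2 fold change was -4.34 (SE 0.54), with an adjusted p of 0.0186 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. The pooled reads gave 20.6 times more Mir155hg in Nf1KO, with a 95% exact binomial interval of 10.7 to 45.8. Nf1, targeted in every tumour (chromosome 11, 79339693 to 79581612), did not differ between groups, at 341 ± 43.3 CPM in miR155KO_Nf1KO and 324 ± 33.2 CPM in Nf1KO. Dhh (chromosome 15, 98891152 to 98898540) was at 612 ± 55.6 and 627 ± 137 CPM and did not differ either. The fall of Mir155hg kept its size but not its call without tumour MiRNC640 (edgeR, Benjamini-Hochberg adjusted p = 0.0518), MiRNC670 (0.0848), Nf803 (0.0838) or Nf827 (0.0668). The Mir155 row itself had 0 reads in all 6 tumours, which allows up to 0.23 CPM in the shallowest library, so the counts do not measure the mature microRNA.

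**Figure D1:**
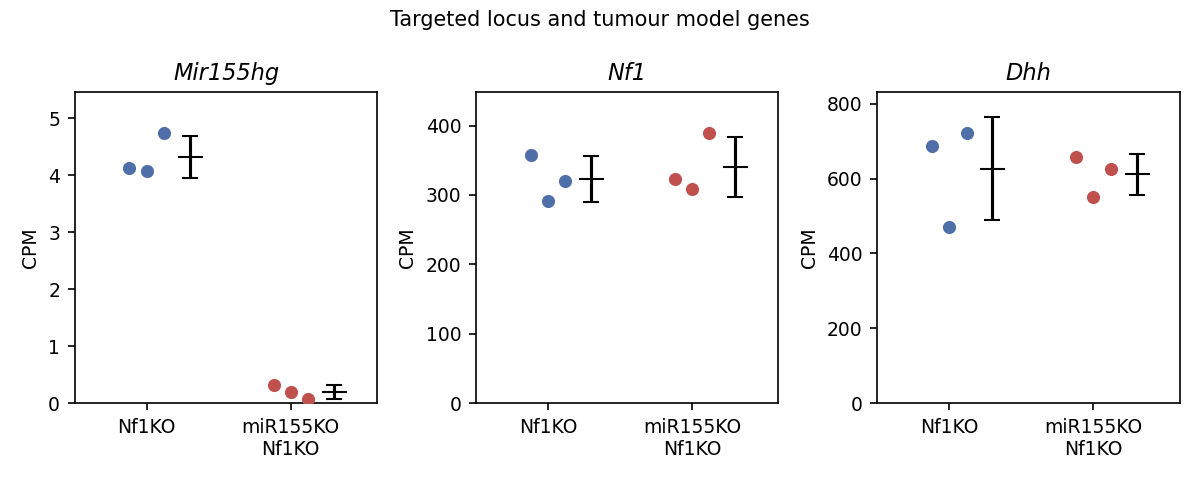
CPM of Mir155hg, Nf1 and Dhh in each tumour (points), with the group mean and SD beside them (bars, n = 3 per group). Mir155hg lay between 4.08 and 4.75 CPM in Nf1KO and at or below 0.322 CPM in miR155KO_Nf1KO, while Nf1 and Dhh overlapped.

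Tumours without miR-155 had higher levels of the neuron and myelin lists and lower levels of the macrophage, dendritic cell, matrix and proliferation lists by camera at a preset correlation, while no list passed with an estimated correlation (smallest adjusted p = 0.197). Of 15604 genes tested, 815 were higher and 739 lower in miR155KO_Nf1KO (9.96% in all), with median changes of 2.71-fold and 2.75-fold. Among the largest rises were Serpina3h, a serine protease inhibitor (chromosome 12, 104247905 to 104253669), from 0.312 ± 0.212 to 7.96 ± 4.95 CPM, and Slc22a2, an organic cation transporter, from 0.228 ± 0.218 to 3.65 ± 0.979 CPM (10 against 154 reads, ratio 16.1, 95% exact binomial interval 8.52 to 34.2). Cndp1, a carnosine dipeptidase, rose from 0.408 ± 0.21 to 6.19 ± 1.99 CPM, Cdh3, which encodes P-cadherin, from 0.307 ± 0.364 to 4.27 ± 0.995 CPM, and Grm8, a metabotropic glutamate receptor, from 0.415 ± 0.244 to 5.55 ± 1.39 CPM. The other rises of this rank were Cyp2j13 (log2 fold change 4.34), Sertm1 (4.32, with 8 against 158 reads and an interval of the ratio from 10.2 to 48.6), Ttll6 (3.77), Pard6b (3.24) and Clstn3 (3.19).

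Among the largest falls was that of Ccr3. This gene, which encodes the eotaxin receptor (chromosome 9, 124021972 to 124031689), had 3 reads in all of miR155KO_Nf1KO against 316 in Nf1KO, a ratio of 101 with a 95% exact binomial interval of 34.2 to 492. Alox15, a lipoxygenase of eosinophils and resident macrophages, fell from 21.3 ± 21.8 to 0.405 ± 0.312 CPM, and H2-Oa, which regulates peptide loading of class II molecules, from 5.21 ± 3.15 to 0.108 ± 0.134 CPM. Klrd1, which encodes CD94 of natural killer cells (chromosome 6, 129591782 to 129598775), fell from 11.8 ± 3.88 to 0.561 ± 0.135 CPM. The chemokine Ccl8 fell by 4.61 on the log2 scale, Gapt, an adaptor of B cells and myeloid cells, by 4.27, Sirpb1a by 4.41, BC147527 by 4.45 and Actc1, cardiac actin, by 5.51. Counting intervals of the ratio between groups were 18.4 to 136 for H2-Oa (5 against 228 reads), 22.6 to 118 for Actc1 (7 against 344), 13.4 to 49.4 for Ccl8 (11 against 280) and 11.7 to 50.2 for BC147527 (9 against 213). Serpina3h, Cyp2j13, Sirpb1a and BC147527 have close copies in the genome, so their counts are uncertain.

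All 1554 called genes had non-overlapping CPM ranges, as did 32.59% of all tested genes, where chance gives 10%. The smallest adjusted p of the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment was 0.0183, and DESeq2 called 1477 genes higher and 1441 lower, with all 1554 among them. With edgeR, 0 genes were called without tumour MiRNC670 (3240 at an unadjusted p under 0.05), without Nf803 (3335) or without Nf827 (3265), and 142 without MiRNC640, whereas DESeq2 called 1876, 2002, 1952 and 2154 in these fits. Sex as a covariate gave 534 genes higher and 502 lower.

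**Figure D2:**
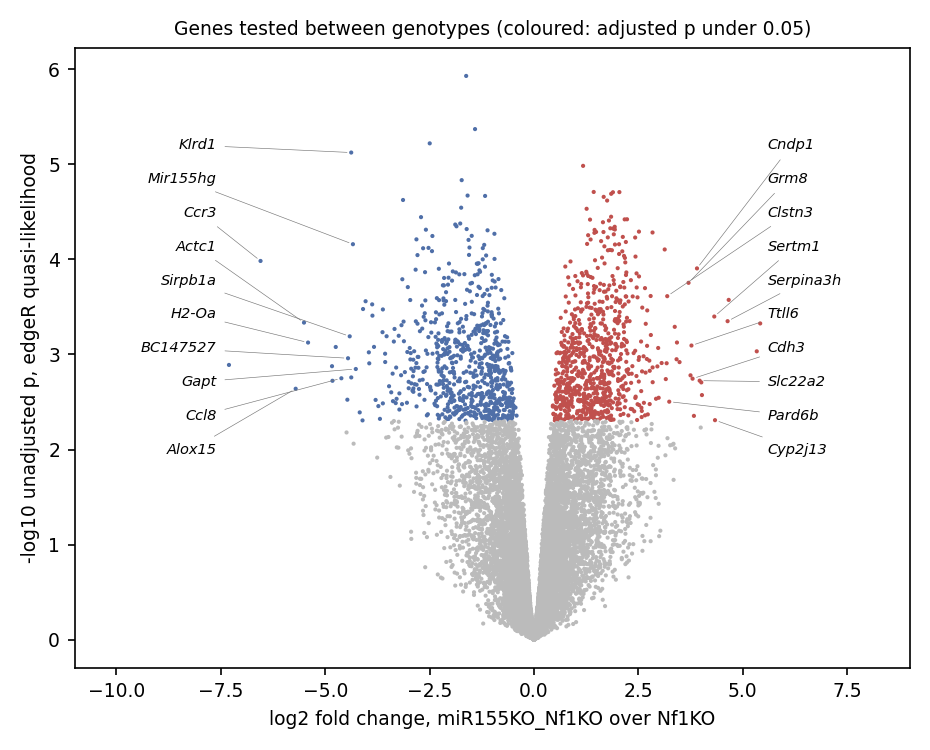
Each point is 1 of the 15604 genes tested, placed by its log2 fold change (miR155KO_Nf1KO over Nf1KO) and the -log10 of its unadjusted p from the edgeR quasi-likelihood test. Coloured points passed the threshold after Benjamini-Hochberg adjustment (815 higher in red, 739 lower in blue), and labels mark the genes with the largest called changes.

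Neuronal transcripts rose as a group. Of 25 tested genes of the sensory neuron list, 13 rose (23 adjusted over the list alone), 0 fell, and the median log2 fold change was 1.69. Snap25, a vesicle fusion protein of nerve endings, rose from 479 ± 171 to 2138 ± 461 CPM (log2 fold change 2.16, SE 0.28), the neurofilament genes Nefm and Nefh by 1.97 (SE 0.29) and 1.82 (SE 0.23), and Isl1, a transcription factor of sensory neurons, by 1.97 (SE 0.30). Myelin genes also rose: 12 of 21 tested members rose (16 adjusted over the list alone), with a median of 1.28, and Gldn, a protein of the node of Ranvier named after its value was seen, fell by 0.84. Drp2 and Prx, partners in the outer layer of the Schwann cell, rose by 1.89 (SE 0.19) and 1.45 (SE 0.25), Ugt8a, which makes the myelin lipid galactocerebroside, by 2.27 (SE 0.35), and the tight junction gene Cldn19 by 1.51 (SE 0.26). The myelin genes Mbp and Pmp22, named after their values were seen, rose by 1.26 and 1.35. The camera adjusted p was 2.62e-11 for neurons (adjusted p = 0.383 with an estimated correlation) and 1.83e-07 for myelin (adjusted p = 0.383 with an estimated correlation). The neuronal mean of tumour Nf809 was 0.755 log2 units above the Nf1KO mean, nearer to the 1.30 to 1.97 of miR155KO_Nf1KO than the other Nf1KO tumours were, while its myelin mean was -0.0844. Within miR155KO_Nf1KO, MiRNC640 was lowest for neurons and highest for myelin (1.44).

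General Schwann cell markers did not move as a group. Of 21 tested, 3 rose and 1 fell (4 and 1 adjusted over the list alone), the median was 0.19, and the camera adjusted p was 0.137 (0.0382 with sex as a covariate). S100b rose by 1.43 (SE 0.15), Fabp7, a lipid-binding protein of immature glia, by 1.77 (SE 0.22) and Gap43, a growth-cone protein, by 1.27 (SE 0.22), while the collagen gene Col28a1 fell by 1.49 (SE 0.18). In the satellite glia list 2 of 8 tested genes rose, Fabp7 again and Ednrb, the endothelin receptor (0.78, SE 0.18), and in the list of central nervous system glia 1 of 8 did, Mal (1.18, SE 0.26), which myelinating Schwann cells also express. Neither list passed camera (adjusted p = 0.27 and 0.553), whereas fry called the satellite glia list (adjusted p = 0.00459).

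Macrophage and dendritic cell transcripts fell, with little distance between tumours MiRNC149 and Nf809: their macrophage means were -0.705 and -0.417 log2 units from the Nf1KO mean, against -1.80 and -1.64 in MiRNC640 and MiRNC670. Tumour Nf809 was also the lowest of Nf1KO for the dendritic cell (-0.739), T cell (-0.700), natural killer cell (-0.635) and interferon (-0.493) lists. Of 22 tested macrophage genes, 7 fell (15 adjusted over the list alone), with a median of -1.57. Itgam, which encodes CD11b, fell from 745 ± 250 to 137 ± 39.8 CPM (log2 fold change -2.44, SE 0.31), Adgre1, which encodes F4/80, by 2.02 (SE 0.37), the mannose receptor gene Mrc1 by 1.48 (SE 0.28) and the growth factor receptor gene Csf1r by 1.68 (SE 0.38). Of 15 tested dendritic cell genes, 10 fell (12 adjusted over the list alone), with a median of -2.27. Cd209a fell from 91.7 ± 64.7 to 7.93 ± 0.369 CPM (log2 fold change -3.53, SE 0.62), the class II gene H2-Ab1 from 1217 ± 836 to 179 ± 43.3 CPM, Xcr1 by 2.98 (SE 0.55) and the transcription factor gene Irf8 by 2.07 (SE 0.39). The camera adjusted p was 4.55e-08 for macrophages (adjusted p = 0.394 with an estimated correlation) and 1.83e-07 for dendritic cells (adjusted p = 0.383 with an estimated correlation).

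Lymphoid lists moved the same way, with few single genes called. The natural killer cell list had a median of -2.01, and Klrd1 was the 1 gene of 8 that fell (3 adjusted over the list alone). Its camera adjusted p was 0.0075 (adjusted p = 0.383 with an estimated correlation). Of 7 tested B and plasma cell genes, Sdc1 (fell by 1.46, SE 0.30) and Jchain (fell by 3.69, SE 0.92) were called, 3 adjusted over the list alone, and the median was -1.46 (camera adjusted p = 0.00945, adjusted p = 0.383 with an estimated correlation). None of 10 T cell genes was called over all genes or adjusted over the list alone by edgeR, although the median was -1.49 and camera gave an adjusted p of 0.00757 (adjusted p = 0.443 with an estimated correlation). Cd28 and Cd8a had log2 fold changes of -2.36 (SE 0.67) and -2.54 (SE 0.76). Mast cell genes, common in neurofibromas, did not move: 0 of 14 were called by edgeR, the median was -0.22 and the camera adjusted p was 0.713. In the neutrophil list Csf3r, the receptor for granulocyte colony-stimulating factor, fell by 1.19 (SE 0.29), the median was -1.22, and the camera adjusted p of 0.2 passed the threshold without tumour Nf827 (0.0296) and with sex as a covariate (0.0489).

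Interferon-induced and inflammatory genes were lower. Of 27 tested interferon response genes, 11 fell (23 adjusted over the list alone), with a median of -1.45. Among them were Oasl2 (fell by 1.75, SE 0.34), Mx1 (fell by 2.89, SE 0.56), Ifit3 (fell by 2.02, SE 0.41) and the guanylate-binding protein gene Gbp3 (fell by 1.52, SE 0.31). Of 20 tested NF-kB and cytokine genes, 2 fell (5 adjusted over the list alone), the adhesion molecule gene Icam1 by 1.87 (SE 0.26) and the apoptosis inhibitor gene Birc3 by 0.91 (SE 0.19), and the median was -0.98. Il1b had a log2 fold change of -2.75 (SE 0.71) and did not pass. The camera adjusted p was 5.60e-10 for the interferon list (adjusted p = 0.383 with an estimated correlation) and 7.32e-06 for the NF-kB list (adjusted p = 0.383 with an estimated correlation).

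Matrix and fibroblast genes fell by smaller amounts. Of 30 extracellular matrix genes, 14 fell and 1 rose (23 and 1 adjusted over the list alone), with a median of -0.76. The basement membrane gene Nid1 fell from 2404 ± 76.4 to 1247 ± 64.2 CPM (log2 fold change -0.95, SE 0.11), Col1a2 from 1658 ± 107 to 920.4 ± 67.3 CPM (-0.85, SE 0.12), the gelatinase gene Mmp2 by 2.05 (SE 0.29) and Loxl2 by 1.23 (SE 0.16). Lox, a collagen cross-linking enzyme named after its value was seen, rose by 1.96. Of 21 fibroblast genes, 8 fell (12 fell and 1 rose adjusted over the list alone), with a median of -0.78, among them Fn1, which encodes fibronectin, from 3286 ± 859 to 981 ± 299 CPM, Postn, which encodes periostin, by 1.57 (SE 0.28) and Fbln2 by 1.31 (SE 0.18). The lists share 4 genes. The camera adjusted p was 3.55e-10 for matrix and 2.46e-05 for fibroblasts (adjusted p = 0.197 with an estimated correlation for each). In the TGF-beta list 4 of 24 genes fell (7 adjusted over the list alone), with a median of -0.60: the activin subunit gene Inhba by 2.62 (SE 0.42), Ltbp1 by 1.57 (SE 0.19), Skil by 1.18 (SE 0.25) and Tgfbr2 by 0.53 (SE 0.13). Its camera adjusted p was 6.82e-04 (adjusted p = 0.197 with an estimated correlation).

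Cell cycle and growth-signal genes were lower. Of 28 tested proliferation genes, 6 fell (10 adjusted over the list alone) and none had a positive log2 fold change, with a median of -1.05. Mki67 fell from 120.1 ± 19.0 to 40.9 ± 9.06 CPM (log2 fold change -1.56, SE 0.20), Ccnb1 by 2.79 (SE 0.36), Top2a by 1.49 (SE 0.26) and Foxm1 by 1.49 (SE 0.33). Of 18 tested ERK target genes, 2 fell (7 adjusted over the list alone), with a median of -0.67: Ccnd1, which encodes cyclin D1, by 1.36 (SE 0.20) and Spred1, an inhibitor of Ras signalling, by 0.91 (SE 0.15). Of 13 p53 target genes 3 fell (3 adjusted over the list alone), Eda2r by 1.88 (SE 0.34), Phlda3 by 0.95 (SE 0.18) and Tnfrsf10b by 1.42 (SE 0.29), and the median was -0.58. By camera, the adjusted p was 1.22e-09 for proliferation (adjusted p = 0.23 with an estimated correlation), 2.65e-04 for ERK targets (adjusted p = 0.383 with an estimated correlation) and 3.57e-04 for p53 targets (adjusted p = 0.383 with an estimated correlation). Ribosomal protein genes had a median of -0.47, with 2 called lower of 24 (1 adjusted over the list alone), among them Rplp0 (fell by 1.22, SE 0.21), and a camera adjusted p of 1.34e-06 (adjusted p = 0.443 with an estimated correlation).

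Cholesterol biosynthesis genes rose, and 2 further metabolic lists moved with single tumours. Of 20 cholesterol genes, 5 rose (10 adjusted over the list alone), with a median of 0.62, among them Hsd17b7 (1.02, SE 0.23), Hmgcs1 (1.10, SE 0.25) and Fdft1 (0.73, SE 0.17). By camera, the adjusted p was 7.01e-05 (adjusted p = 0.443 with an estimated correlation). None of 24 oxidative phosphorylation genes was called by edgeR, over all genes or adjusted over the list alone, although all 24 had a positive log2 fold change, with a median of 0.66. Ndufa4 had a log2 fold change of 0.92 (SE 0.24). The camera adjusted p was 5.00e-04 (adjusted p = 0.639 with an estimated correlation) and 0.0591 without tumour MiRNC640, and the list means were 1.11 and 0.591 above Nf1KO in tumours MiRNC640 and MiRNC670 and -0.0732 in tumour MiRNC149. None of 15 adipocyte genes was called by edgeR, with a median of 1.96. The list passed camera (adjusted p = 0.0305, adjusted p = 0.673 with an estimated correlation) but not without tumour MiRNC640 (0.392), MiRNC670 (0.0545) or Nf809 (0.459), without MiRNC670 and Nf809 (0.483), with sex as a covariate (0.0525) or with voom quality weights (0.0616), and tumour MiRNC640 stood highest, at 3.51 log2 units above the Nf1KO mean, with Nf809 lowest at -1.89.

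Other cell types and pathways did not pass camera with all 6 tumours, though some passed under other settings. Skeletal muscle genes were high in tumours Nf809 and MiRNC670 (list means 4.15 and 3.66 log2 units above the Nf1KO mean) and low in Nf827 (-3.39), and 0 of 21 were called by edgeR. The median of their log2 fold changes was -0.18 while camera, on log2 CPM, put the list up (adjusted p = 0.0764, 8.26e-07 without tumour Nf809, 0.0318 without MiRNC149, 0.0453 with upper quartile scaling, 0.0469 with voom, 7.19e-04 with voom quality weights, 4.27e-07 without tumours MiRNC670 and Nf809 and 8.75e-08 without MiRNC149 and Nf809). None of 15 endothelial genes was called by edgeR, with a median of 0.39, Cldn5 at 1.48 (SE 0.47) and a camera adjusted p of 0.369 (0.0465 without tumours MiRNC149 and Nf809), and none of 12 pericyte and smooth muscle genes, with a median of -0.46 and a camera adjusted p of 0.179 (0.0202 with sex as a covariate). In the perineurial list Casq2 fell by 1.51 (SE 0.29) and the tight junction gene Cldn1 by 1.70 (SE 0.39), with a camera adjusted p of 0.369. In the cartilage and bone list Col2a1 fell by 1.33 (SE 0.25) and Runx2 by 0.93 (SE 0.22), with a camera adjusted p of 0.125. Nr4a2 rose by 1.05 (SE 0.18) among 24 immediate early genes (median -0.38, camera adjusted p = 0.0699, 0.0113 without tumour MiRNC149, 0.0214 without MiRNC149 and Nf809, and 0.0426 with voom quality weights). Asns rose by 0.80 (SE 0.20) among 16 genes of the unfolded protein response (median -0.39, camera adjusted p = 0.0928, 0.0452 with voom and 0.0426 with voom quality weights). In the hypoxia list Bnip3 and Ndrg1 rose by 1.20 and 0.66 and P4ha1 fell by 0.53 (camera adjusted p = 0.827). Among 20 Ras regulators Rasal2 rose by 0.85 (SE 0.21) and Spred1 fell, and the median of 0.05 and the downward camera test (adjusted p = 0.883) differ in sign. The circadian clock (median -0.11) and JAK-STAT (median -0.22) lists had no gene called by edgeR, with camera adjusted p of 0.892 and 0.217. Cdh1, which encodes E-cadherin, rose by 1.45 (SE 0.17) among 4 tested epithelial genes, and none of 3 erythroid genes was called.

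With camera, 19 of the 35 lists passed, 5 up and 14 down. Fry called 12, of which 11 were among the 19 and the other was satellite glia, and it did not call the macrophage, T cell, interferon, NF-kB, adipocyte, oxidative phosphorylation, ribosomal protein and cholesterol lists. With an estimated correlation 0 lists passed and 4 had an unadjusted p under 0.05.

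**Figure D3:**
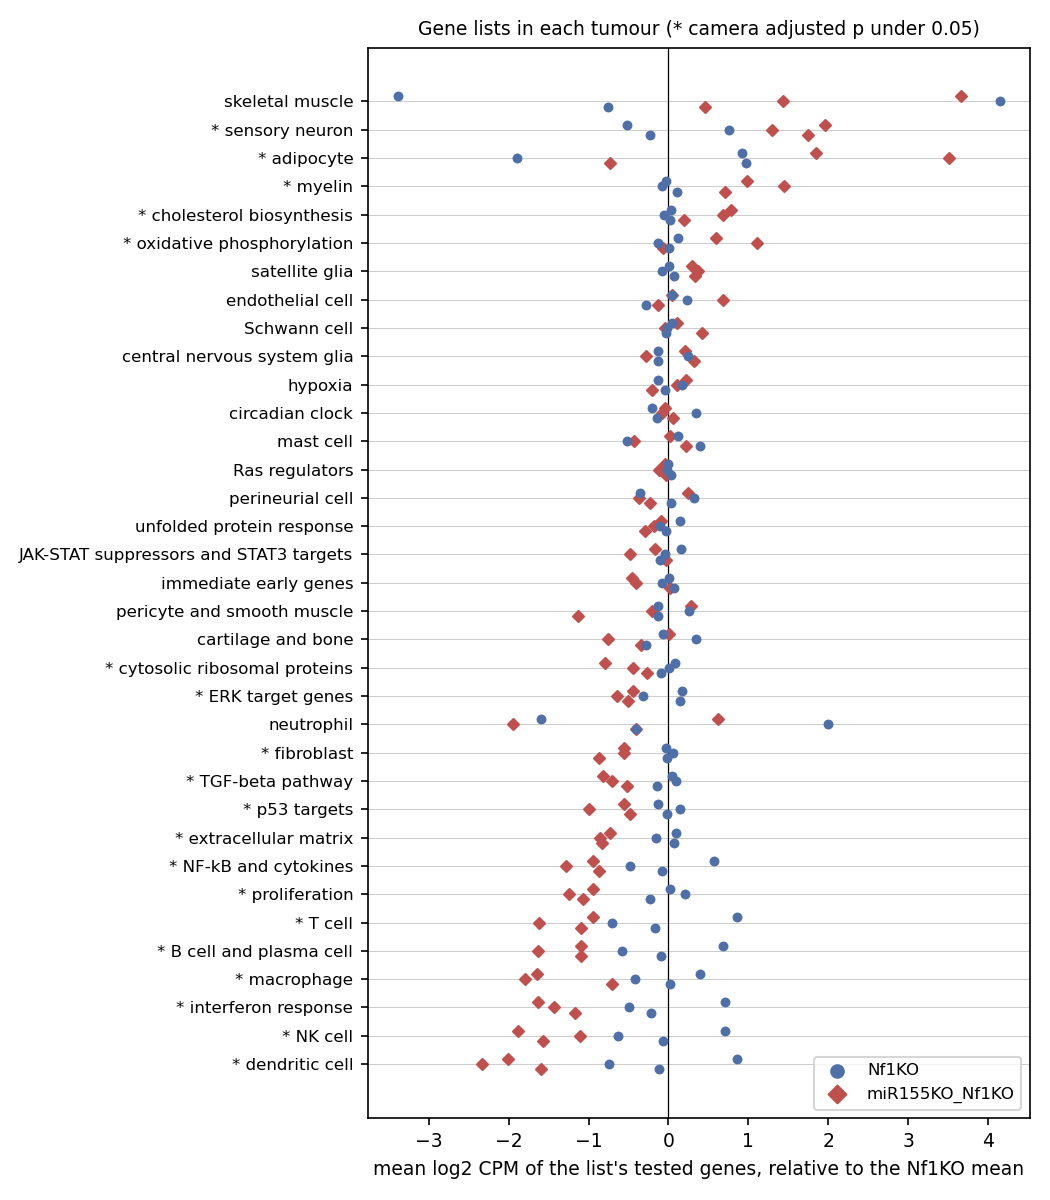
Mean log2 CPM of the tested genes of each list in each tumour, relative to the mean of the 3 Nf1KO tumours (circles Nf1KO, diamonds miR155KO_Nf1KO, stars lists with a camera adjusted p under 0.05). The dendritic cell list lay between -2.33 and -1.60 in miR155KO_Nf1KO and the sensory neuron list between 1.30 and 1.97. Adipocyte and skeletal muscle means varied most within miR155KO_Nf1KO (SD 2.13 and 1.64), and skeletal muscle and neutrophil means within Nf1KO (SD 3.82 and 1.83).

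The genotypes separated on the main axis of expression. The first principal component of log2 CPM held 50.45% of the variance and placed the miR155KO_Nf1KO tumours from -65.8 to -26.5 and the Nf1KO tumours from 13.1 (tumour Nf809) to 81.4. The second held 20.77%, with tumour Nf809 at 68.7 and tumour MiRNC640 at -41.2. With the 500 most variable genes alone, tumour Nf809 fell on the side of miR155KO_Nf1KO on the first component (-14.4). Pearson correlations across genes, which are not independent replicates, were 0.913 to 0.965 within groups and 0.867 to 0.936 between them.

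Known miR-155 targets were not higher as a group in tumours without it. Of 42 targets taken from the literature, 40 were tested, 0 rose and 5 fell (0 and 8 adjusted over the list alone), and the median log2 fold change was -0.26. Among those that fell were Trps1, a transcription factor (-1.21, SE 0.19), Spi1, the myeloid factor PU.1 (-1.91, SE 0.39), Csf1r (-1.68, SE 0.38) and Inpp5d, the leukocyte phosphatase SHIP1 (-1.73, SE 0.43). Of these, Inpp5d was named after its value was seen. Spi1 has an 8mer site at chromosome 2, 91115437 to 91115444, and Inpp5d at chromosome 1, 87719838 to 87719845, each in an exon of the 3′ UTR. Csf1r, with a site at chromosome 18, 61131123 to 61131130, also stands in the macrophage list, whose genes fell by a median of 1.57. Counts of whole pieces do not separate a change within cells from a change in the share of cells. A rise of these targets within cells is therefore not excluded. The camera test put the list down with p = 1.44e-04 (p = 0.0783 with an estimated correlation), and fry gave p = 0.00595. Of the 40, 31 had a site in the 3′ UTR, and their median was -0.34.

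Across all mRNAs, a miR-155 site in the 3′ UTR went with no rise beyond that of shuffled sites. The 1985 tested genes with a site had a median log2 fold change of 0.05 and the 12030 without one a median of -0.00, and after matching on 3′ UTR length and expression the shift was 0.00583 log2 units. Of 419 shuffled control sites, 297 gave a shift as large, and the middle 95% of them ran from -0.0142 to 0.0491. With 1 tumour left out the shift ran from -0.00594 (without MiRNC149, where its sign turned) to 0.0225 (without MiRNC670), and voom quality weights gave 0.0263, at percentile 87.8 of the controls. Camera gave p = 0.203 (p = 0.239 with an estimated correlation), whereas fry, which does not compare the set with other genes, gave p = 0.0304 upward. Genes with a site were called higher more often than genes without one, 152 of 1985 (7.66%) against 612 of 12030 (5.09%), with p = 8.73e-06 by Fisher's exact test, two-sided. Shuffled sites gave a median share of 8.05% called higher, and 300 of 419 gave a share as large as that of miR-155. The controls that take in miR-155 sites, GCATTAA (7.42%) and AAGCATT (7.47%), are not among those 300. Genes with a site were called lower less often, 72 of 1985 (3.63%) against 632 of 12030 (5.25%), with p = 0.00185 by Fisher's exact test, two-sided. Shuffled sites gave a median share of 4.8% called lower, and 408 of 419 gave a share as large, which puts miR-155 at percentile 2.63. Genes with a site had a median 3′ UTR of 2670 bases and genes without one 1048.

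The 8mer genes with the smallest p in the upward direction included Pcdh9, a protocadherin, which rose from 58.3 ± 13.4 to 196 ± 18.9 CPM and has its site in the 3′ UTR exon at chromosome 14, 93015055 to 93015062. Trim67, a neuronal ubiquitin ligase, rose from 9.24 ± 0.81 to 35.5 ± 10.6 CPM, with a site at chromosome 8, 124832727 to 124832734. Sema5a, an axon guidance protein, rose from 283 ± 23.6 to 794 ± 219.9 CPM (site at chromosome 15, 32690518 to 32690525), and Tgfa, a ligand of the epidermal growth factor receptor, from 12.2 ± 1.62 to 46.9 ± 19.8 CPM (site at chromosome 6, 86272948 to 86272955). Tomm20, of the mitochondrial import machinery, rose by 0.85 (SE 0.12), and the others were Strbp (0.94), Nrip3 (1.30), Entpd3 (2.48), Stxbp5l (2.05) and Ttl (1.08), all in log2 units. Over all 487 genes with an 8mer site the matched shift was -0.00519.

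**Figure D4:**
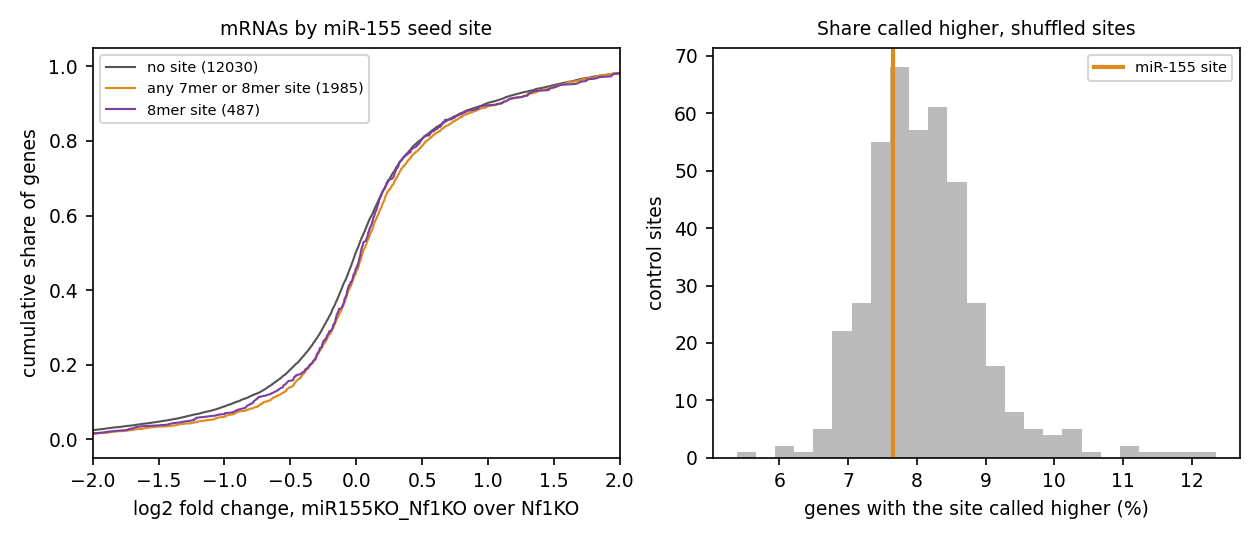
Left, the cumulative share of genes by log2 fold change (miR155KO_Nf1KO over Nf1KO) for genes without a miR-155 site (12030), with any site (1985) and with an 8mer site (487). Right, the percentage of genes called higher among genes that hold each of 419 shuffled control sites (grey), where the miR-155 site (line, 7.66%) lies below the control median of 8.05%.

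Genes around the Mir155 locus were not called more often than genes elsewhere. Within 10 Mb, 7 of 75 genes were called (9.33%), against 1508 of 14932 elsewhere (10.1%), an odds ratio of 0.916 with p = 1 by Fisher's exact test, two-sided. The nearest called gene, named after its value was seen, was Adamts1, a matrix protease (chromosome 16, 85793827 to 85803113, 1.09 Mb away), which fell from 227 to 73.7 CPM. Its edgeR adjusted p of 0.0183 equals the smallest of all genes tested. The Fisher test weighs only the number of calls, so an effect of the altered locus on single genes nearby stays open. The next, named likewise, was Grik1, a kainate receptor subunit gene at 3.38 Mb, which rose from 8.45 to 52.6 CPM.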

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

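The tests in this part were chosen after the result was seen. An interaction term of sex and genotype called 46 genes in edgeR's quasi-likelihood test (smallest Benjamini-Hochberg adjusted p = 0.00511, 1871 genes at an unadjusted p under 0.05, 2 residual degrees of freedom). Tumour MiRNC149 is the lone female of miR155KO_Nf1KO and tumour Nf809 the lone male of Nf1KO, so by design the term sets these 2 tumours against the other 4, and genes it calls must tend to be high in both (22 of the 46) or low in both (21). Over all tested genes 13.7% were highest or lowest in both, where chance gives 13.3%. A list of glucocorticoid response genes was written after these values were seen, so its 8 members among the 46 are no test of that theme. Of these, Fkbp5 stood at 129 and 160 CPM against 9.84 to 21.1 CPM, and Tsc22d3 at 159 and 221 CPM against 17.1 to 26.3 CPM. The adipocyte list, fixed before the data were examined, had 3 of its 15 tested genes among the 46, 2 of them Ucp1 and Plin1: Ucp1 stood at 5.28 and 2.04 CPM against 107 to 371 CPM, and Plin1 at 11.1 and 3.65 CPM against 35.7 to 224 CPM.

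A candidate explanation is that the pieces of tumours MiRNC149 and Nf809 held less fat. The 12 adipocyte genes outside the 46 had a lower mean in both tumours than in the other 4, with a gap of 1.23 log2 units. Genes of this list moved closely together (estimated correlation 0.897), so these 12 were likely to follow the 3 among the 46 and are no independent test. For a glucocorticoid response no test was possible: the list was written after the values were seen, so the gap of 0.737 log2 units of its 14 tested genes outside the 46 decides nothing. An effect of sex on the response to genotype cannot be told apart from it, because the smallest cell of sex and genotype holds 1 tumour. Without tumours MiRNC149 and Nf809 edgeR called 1562 genes higher and 1394 lower between genotypes, with 1418 of the 1554 genes among them.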

How the results depend on the processing

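No called result reversed. The fits without tumours MiRNC670 and Nf809 or MiRNC149 and Nf809, and DESeq2 with 1 tumour left out, were chosen after the data were seen. Genes higher and lower numbered 815 and 739 and came to 1477 and 1441 with DESeq2, 1485 and 1190 with voom quality weights, 1562 and 1394 without tumours MiRNC149 and Nf809, 1383 and 1319 at an adjusted p under 0.1, and 0 and 0 at 0.01, where the smallest edgeR adjusted p was 0.0183. Sex as a covariate gave 534 higher. Leaving out 1 tumour gave 0 to 1183 higher and 0 to 1059 lower with edgeR, and 1876 (without MiRNC670) to 3304 with DESeq2. Fewer samples leave fewer residual degrees of freedom, but the loss of calls depended on the tumour left out. With edgeR, 2242 genes were called without Nf809 and 1475 without MiRNC149, against 0 without MiRNC670, Nf803 or Nf827. All 1554 genes called with 6 tumours kept their sign and an unadjusted edgeR p under 0.05 in each of the 6 fits. They were chosen with the same tumours, so this is no independent test. Other scalings and filters stayed within 1.5 times, and scaling moved the median of all genes by less than 0.1 log2 units. The log2 fold change of Mir155hg ran from -4.82 to -4.02 with 1 tumour left out. Of the 20 genes with the largest called changes, 10 passed with voom, 13 without tumours MiRNC670 and Nf809, and 0 to 19 with 1 tumour left out. Of 19 lists called, 9 of them cell types, 0 passed with an estimated correlation. Fry called 12 lists, 11 of them among the 19. The literature list had p = 0.0783 with an estimated correlation, and the site genes p = 0.0304 with fry. The first principal component held 52.24% with the 500 most variable genes. Odds ratios near Mir155 were 1.05 within 5 Mb and 1.22 within 20 Mb. The cause was not tested for these changes. Over 189 named genes, 2050 of 2260 comparisons with other settings kept their direction and side of the threshold, and 677 of 1134 with 1 tumour left out. Camera was not run under DESeq2 or edgeR with robust estimation. No paired analysis was possible because the groups share no replicate number. No read was counted for 4229 symbols in any tumour.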

Other observations

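Gene families grouped by symbol stem, a grouping chosen after the data were seen, were compared without the members of the fixed lists. For 188 stems with at least 10 tested genes, each direction was tested by Fisher's exact test with Benjamini-Hochberg adjustment over 376 tests. The test treats genes as independent and does not measure the spread between tumours. Genes of the fixed macrophage and dendritic cell lists moved together (estimated correlation 0.598 and 0.518). The adjusted p-values of families that move together are therefore too small, and such families need not be separate findings. Kinesin genes were called higher more often than other genes (8 of 32 Kif genes outside the lists, adjusted p = 0.0107), among them the axonal motors Kif1a (509 to 1108 CPM) and Kif5a (113 to 381 CPM). So were Fgf genes (5 of 12, adjusted p = 0.0107), with Fgf9, Fgf12 and Fgf13 among them, genes with the stem Atp, which holds pumps and ATP synthase subunits (12 of 68, adjusted p = 0.0107), and Mapk genes (5 of 16, adjusted p = 0.035). Synaptotagmins and cadherins passed with list members (5 of 13 Syt genes, adjusted p = 0.0133, and 5 of 17 Cdh genes, adjusted p = 0.0359) but not without them (adjusted p = 0.0782 and 0.119). Zinc finger genes with the stem Zfp were called less often in both directions (4 of 339 higher, adjusted p = 0.00927, and 3 of 339 lower, adjusted p = 0.0173).

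Other stems were called lower more often, again outside the fixed lists and with the same limit of the test. Fisher's exact test gave 14 of 60 Cd genes (adjusted p = 5.53e-05), with the costimulatory ligand gene Cd80 at 4.88 against 29.4 CPM and Cd72 at 1.47 against 21.7 CPM. It gave 5 of 10 Ccl chemokine genes (0.00535) with Ccl11, the ligand of the receptor Ccr3, at 228 against 582 CPM, 6 of 20 C-type lectin genes (Clec, 0.0107), 4 of 8 interferon-inducible Ifi genes (0.0107), 5 of 15 Tnfrsf genes (0.0107), 8 of 38 interleukin and interleukin receptor genes (Il, 0.0107) and 4 of 12 Toll-like receptor genes (0.035). Collagens fell in 11 of 41 cases (adjusted p = 2.95e-04), but 8 of the 11 stand in the fixed lists, and the 25 outside them did not pass (adjusted p = 0.716). Slc genes were called lower less often with list members (3 of 283, adjusted p = 0.0348) and did not pass without them (adjusted p = 0.0962).

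The matched shift of 8mer genes was planned, and the other tests in this part were chosen after the result they weigh was seen: that of the control sites was written after the excess of calls among site genes, and before the share of calls at the control sites was computed. The sensory neuron and myelin lists were higher and the macrophage, dendritic cell, interferon and matrix lists lower together. More tissue with neuron and myelin transcripts in the piece, called nerve here, would dilute every other cell type alike. The counts do not show which neuronal tissue it was. Relative to the endothelial mean the macrophage mean changed by -1.58 log2 units (SE 0.642). This does not decide, since MiRNC149 (-0.573) and Nf809 (-0.654) overlap (exact permutation p = 0.2). The dendritic cell, matrix and interferon means changed by -2.18, -1.01 and -1.61 against the same mean without overlap, where 0.1 is the smallest exact permutation p that 3 against 3 tumours allow. Sex does not account for it as a whole: with sex as a covariate the 69 called genes of 6 of these lists kept 0.877 times their median change, and 53 stayed called. The mast cell mean changed by -0.0615 log2 units (SD 0.332 in miR155KO_Nf1KO and 0.465 in Nf1KO). The dendritic cell mean itself changed by -1.98 (SD 0.367 and 0.802). Equal dilution forbids such unlike changes, so these values argue against it as the sole source of the dendritic cell fall. A smaller infiltrate in tumours without miR-155, dilution in part, and pieces that differ in nerve content with the vessels that nerve brings all stay open and may act together.

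Genes with a miR-155 site were called higher more often than genes without one, which could be read as release from repression. The share of 7.66% stood at percentile 28.4 of the 419 control sites, so the values argue against release from repression as the source of this excess and are consistent with the long 3′ UTRs of the genes called higher, whose median was 1944 bases against 1216 for genes called lower. The share called lower, 3.63% at percentile 2.63 of the same controls (median 4.8%), lies near the low end of their middle 95% but inside it. Among controls with a lower share, AACTAGT (3.46%, 1387 genes) was alone in being held by many genes. The others were held by 524 genes or fewer, such as AACGTTA (2.48%, 524 genes) and ATAATCG (3.59%, 251 genes). Shares of so few genes vary more, so the percentile over all controls understates how low the share was. Against controls held by more than 524 genes, the miR-155 share called lower was unusually low. What lowered it was not tested. Genes with an 8mer site, where release should be strongest, were called higher in 37 of 487 cases (7.6% against 5.09% without a site, p = 0.0211 by Fisher's exact test). They were called lower in 22 (4.52% against 5.25% without a site, p = 0.534 by Fisher's exact test). No control sites were computed for the 8mer, so its excess of calls was not set against shuffled sites. The matched shift of the 8mer genes, which takes 3′ UTR length into account, was -0.00519. An effect on single genes stays open, since these values cover the site genes as a set.

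The 6 tumours can be split into 3 and 3 in 10 ways, too few for a share under 0.05, so only the values are given, for tests chosen after the results were seen. The real split called 1554 genes and the highest other 5. For lists the real split called 19 and the others from 6 to 18, where 18 came from the split of females from males. Camera at the preset correlation thus called lists under every split. For the literature targets the -log10 p of camera was 3.84 with the real split and 2.88 with the highest other. For the size of the matched shift of site genes the values were 0.00583 and 0.0123. Of the 10 splits 6, the real one among them, reached 0.00583.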
